A study of Mus musculus with 103 samples.

How the data were processed

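The study profiled the aortic arch of ovariectomized female C57BL/6 mice, wild type or ApoE knockout, by Illumina TruSeq stranded mRNA sequencing. Mice ate a diet with 42% of calories from fat and were given vehicle or 10 mg/kg Scl-Ab by weekly subcutaneous injection for 3, 8 or 16 weeks (day22, day57 and day113 in the labels), when they were 12 to 13, 17 to 18 and 25 to 26 weeks old. There were 31 libraries in week 3, 34 in week 8 and 38 in week 16, with 1 animal per library, in 12 groups of 5 to 10. The study's text speaks of sequencing in 3 batches without assigning them to libraries, so batch could not be put in a model, and comparisons between days may include a difference between batches.

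The deposited files hold 1 value per gene symbol and library in fpkm, in a column called FPKQ. The labels do not define FPKQ. Scaling to a shared high quantile of the genes was inferred from the values alone, which have no fixed total, since column sums ran from 494635.2 to 826445.4. Genome build GRCm38 and DESeq2 1.10.1 are named per the submitters' processing notes. The aligner, the quantifier, the annotation and the use of strand in counting are not given in the sources used here, and read counts cannot be recovered from the values. Symbols numbered 51456, with no mitochondrial ones, and 1 file had no header line. Of the symbols 45797 (89%) matched 1 gene of GENCODE M21, as did 97.4% of those tested. Values of paralogs, pseudogenes and overlapping antisense genes are by symbol alone.

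Sequencing depth in reads is unknown. Relative depth was taken from the most common ratio between libraries of values under 1. There, libraries with the same small number of reads of a gene differ by the value given to 1 read. That value follows depth, but with scaling to a shared quantile it can also follow the composition of a library. The measure is thus an approximation of depth. It ran from 0.821 to 1.59, with a mean of 1.24 ± 0.192 in knockout Scl-Ab libraries of week 8 and means of 0.920 to 1.15 in the other groups. Between 12405 and 13338 genes reached a value of 1 in a library. No 2 libraries held identical values, and the median correlation with the own group was 0.902 at its lowest and 0.981 at its median. No confidence interval for counting error can be given without counts.

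Groups were read from the labels. Genes with a value of at least 1 in at least 5 libraries were kept (14637), and log2(value + 1) was fitted with a mean per group in limma 3.58.1 (R 4.3.3; trend and robust empirical Bayes). The offset of 1 makes log2 changes of low genes smaller than the ratio of their values. Contrasts compared genotypes within treatment and day, treatments within genotype and day, the treatment response between genotypes, the means over the 3 times, and the genotype effect between days. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. Gene lists, 34 of cell types and pathways, were tested with camera at a preset correlation of 0.01 where at least 4 members were measured, with adjustment over the lists of a comparison, and again with an estimated correlation. A clock score of all 15 genes of the list was compared between groups by exact permutation tests over all splits of the libraries, two-sided, with adjustment over 12 tests.

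The comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. Named in any comparison were Apoe, Sost, Axin2, Dkk1, Runx2, Spp1, Bglap, Alpl, Mgp, Tnfrsf11b, Cd68, Ccl2, Il1b and Acta2. To these were added up to 8 called genes with the highest and 8 with the lowest change and a mean of at least 1 in the higher group (predicted genes, pseudogenes and antigen receptor segments left out), up to 4 called members of each list by adjusted p, and all genes of a comparison with 5 or fewer calls. Dkk1 did not reach the filter. The clock scores and the components of clock genes were chosen after the data were seen.

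Alternatives were a pseudocount of 0.1, no filter on low values, a filter of 5, rescaling by median of ratios (factors 0.934 to 1.04), quantile normalization, fits on a day or on the compared groups alone, array weights, a block for replicate number, a 1.5-fold minimum, leaving out each library of the compared groups in turn (for counts of genes within a day, not gene by gene; for contrasts across days only the 5 wild-type vehicle libraries of week 8), and carry-over scores as covariates. These scores are the mean log2 value of the white adipocyte, brown adipocyte, skeletal muscle, cardiomyocyte and thymocyte lists, 5 tissues that lie against the arch. Chosen after the data were seen were the first 2 principal components of the circadian clock list as covariates, alone or with the carry-over scores, leaving out 29 libraries whose score lay over 2.5 median absolute deviations above the median, and the run of animal numbers as a covariate. No scaling moved the median change of all genes by more than 0.1. The pipeline was tested on simulated data with the sizes and spread of 3 comparisons, where 77.6% to 85.1% of genes changed 1.5-fold and 91.04% to 94.0% of genes changed 2-fold were recovered, with 12 to 15 false calls. Noise was independent per gene and folds were added to log2(value + 1), so this tested the pipeline and not the power in the real libraries. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table (version 1.17.8).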

Results

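Expression in the aortic arch was read from 31, 34 and 38 RNA-seq libraries, taken after 3, 8 and 16 weeks of dosing (day22, day57 and day113 in the labels), of separate ovariectomized female C57BL/6 mice on a diet with 42% of calories from fat. Wild-type mice and mice without apolipoprotein E, the ligand for hepatic uptake of remnant lipoproteins, had been given vehicle or Scl-Ab. Scl-Ab is the antibody r13C7 against sclerostin, the Wnt antagonist encoded by Sost, and was injected at 10 mg/kg once weekly. Week 3 had 8 wild-type vehicle, 8 knockout vehicle, 6 wild-type Scl-Ab and 9 knockout Scl-Ab libraries. Week 8 had 5, 10, 9 and 10 in the same order, and week 16 had 10, 10, 8 and 10. The files hold no read counts, so depth was only approximated, relative to the median library, from 0.821 to 1.59, and composition was not separated from it. Group values are deposited fpkm-type values (mean ± SD), changes are log2 differences ± SE, and adjusted p-values come from limma over 14637 genes.

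Apoe separated the genotypes completely. In vehicle libraries the gene, at 19696109 to 19699188 on chromosome 7 of GRCm38 (protein-coding, GENCODE M21), fell from 361 ± 81.2 to 8.27 ± 1.66 in week 3, a log2 change of -5.28 ± 0.17 (adjusted p 9.67e-47, n = 8 and 8). The change was -5.24 ± 0.19 in week 8 and -5.21 ± 0.15 in week 16. The lowest of all wild-type libraries stood at 219.9 and the highest of all knockout libraries at 18.24, Scl-Ab libraries included.

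Knockout aortas of week 3 carried more transcripts of lipid-laden macrophages than wild-type aortas under vehicle. Cd68, a late endosomal glycoprotein of macrophages, rose from 6.96 ± 2.81 to 58.4 ± 43.3 (log2 change 2.72 ± 0.24, adjusted p 1.14e-16, n = 8 and 8), and the ranges of 3.60 to 10.9 and 22.3 to 158 did not overlap. Cd5l, a survival factor secreted by tissue macrophages, rose by 6.10 ± 0.35, the macrophage elastase gene Mmp12 by 4.59 ± 0.28, and Spp1, the matrix phosphoprotein osteopontin, by 4.21 ± 0.57. Of 18 foamy macrophage genes 15 were higher (adjusted over the list alone, 16 higher and 1 lower; median log2 change 2.03). Of 20 general macrophage genes 18 were higher (20 adjusted over the list alone), as were 22 of 23 cytokine and chemokine genes (22 over the list alone) and 11 of 12 leukocyte adhesion genes (12 over the list alone). The monocyte attractant Ccl2 rose by 2.31 ± 0.38 and the inflammasome product Il1b by 0.96 ± 0.25 (adjusted p 0.00264). Icam1, an endothelial docking molecule for leukocytes, rose by 1.28 ± 0.17, and the cholesterol exporter gene Abcg1 by 2.36 ± 0.20, along with 7 of 11 targets of the oxysterol receptor LXR (7 over the list alone).

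Fkbp5, Errfi1 and Acta2 were among the lower transcripts of week 3. Fkbp5, a co-chaperone induced by glucocorticoid, fell from 161 ± 77.5 to 66.8 ± 47.0 (log2 change -1.45 ± 0.45, adjusted p 0.0140, n = 8 and 8), a change that turned to 0.123 with components of the clock genes in the model. Errfi1, a feedback inhibitor of the EGF receptor, changed by -2.29 ± 0.39. The smooth muscle actin gene Acta2 changed by -0.59 ± 0.18 (adjusted p 0.0125) and the elastin gene Eln by -0.82 ± 0.27 (adjusted p 0.0191). Sost (log2 change -0.45 ± 0.22, adjusted p 0.112) and the Wnt feedback gene Axin2 (0.19 ± 0.14, adjusted p 0.316) did not pass. In limma 3648 genes passed, 1692 higher and 1956 lower, with 958 of them at least 1.5-fold. With an estimated correlation between list members, camera kept the foamy macrophage (adjusted p 0.00257), macrophage (0.0276), cytokine (0.0282), adhesion (0.00906) and LXR (0.00906) calls. It lost the calls of the interferon response (17 of 18 higher, 18 over the list alone; 0.134), lysosome (13 of 20, 14 over the list alone; 0.234) and smooth muscle lists (7 of 15 lower, 8 over the list alone; 0.462). The count was 5901 without wild-type vehicle replicate 4 and 2407 without replicate 7. It was 1953 with scores of carried-over tissue in the model and 840 with components of the clock genes.

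**Figure D1:**
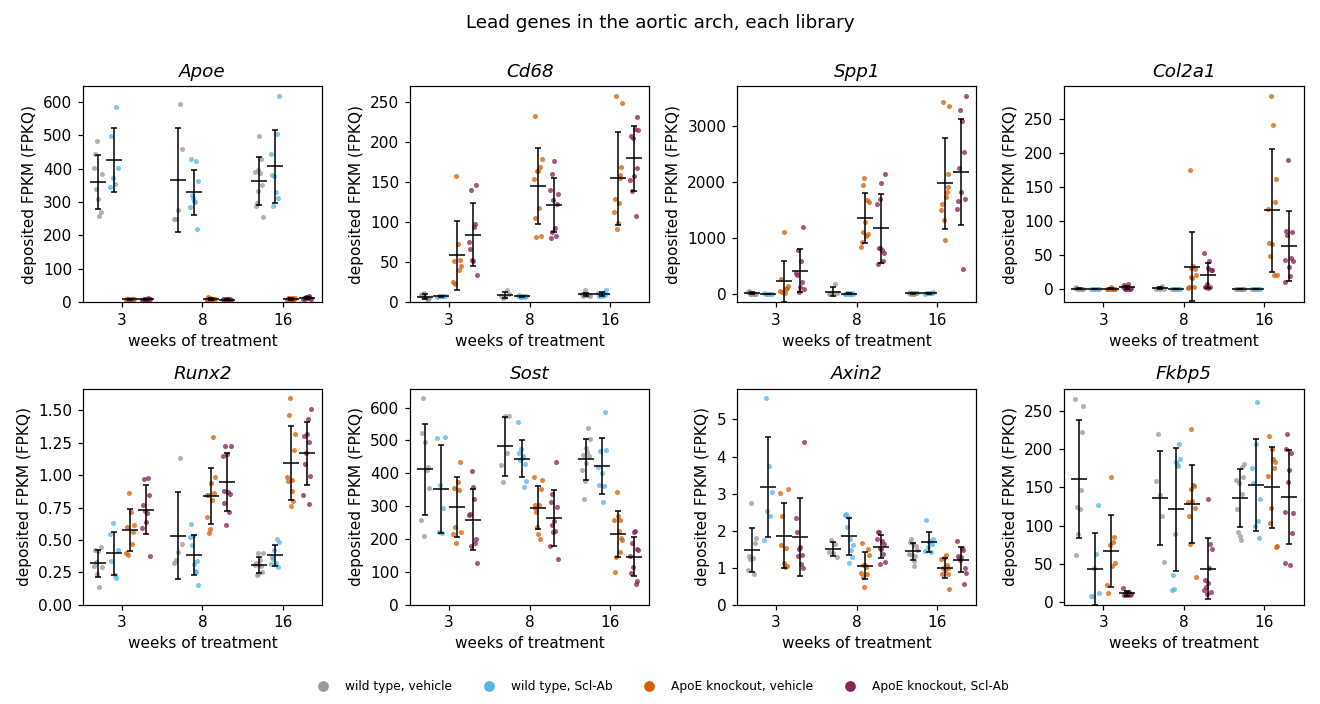
Deposited values of 8 genes (y axis) in each library (points) by weeks of treatment (x axis), with colour for genotype and treatment and bars for group mean and SD. Apoe stayed at or above 219.9 in wild type and at or below 18.24 in the knockout.

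In week 8 macrophage genes were again higher in the knockout, and a cartilage collagen gene was higher too. Spp1 rose from 40.1 ± 76.4 to 1358 ± 442 (log2 change 6.84 ± 0.63, adjusted p 4.99e-16, n = 5 and 10), with ranges of 1.59 to 177 and 844 to 2075. Cd68 rose by 3.88 ± 0.26, and Col2a1, the fibrillar collagen of cartilage, by 3.28 ± 0.59 (adjusted p 7.74e-06). Of the foamy macrophage genes 14 of 18 were higher (16 over the list alone; median log2 change 2.99), and so were 20 of 20 lysosome genes (20 over the list alone; median 0.70). The osteoblast transcription factor gene Runx2 rose by 0.28 ± 0.09 (adjusted p 0.0222) and the phosphatase gene Alpl, whose product removes the mineralization inhibitor pyrophosphate, by 0.62 ± 0.22 (adjusted p 0.0420). Sost fell from 482 ± 89.8 to 295 ± 65.1 (log2 change -0.72 ± 0.24, adjusted p 0.0285), a call that ended with replicate number as a block and without a filter on low values. Il1b (0.71 ± 0.27, adjusted p 0.0568) and Acta2 (-0.14 ± 0.20, adjusted p 0.677) did not pass. In limma 2268 genes passed, 1490 of them higher. The calls of the foamy macrophage (adjusted p 2.27e-05) and lysosome (0.0117) lists held with an estimated correlation. The wild-type group was the smallest of the study, and with carried-over tissue scores in the model 3883 genes passed.

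Bone and cartilage genes stood above wild type in vehicle-treated knockouts after 16 weeks. In week 16 Spp1 rose from 6.72 ± 5.38 to 1978 ± 814 (log2 change 8.12 ± 0.51, adjusted p 1.23e-25, n = 10 and 10) and Col2a1 from 0.152 ± 0.104 to 115.4 ± 90.3 (6.20 ± 0.48), with ranges of 0.0128 to 0.389 and 20.1 to 283. Ibsp, the bone sialoprotein of mineralizing matrix, rose by 4.43 ± 0.42, Runx2 by 0.67 ± 0.07 (adjusted p 5.04e-13), Alpl by 1.38 ± 0.18, and the osteocalcin gene Bglap by 0.85 ± 0.16. Inhibitors of mineral growth were higher as well: Tnfrsf11b, the decoy receptor osteoprotegerin, by 1.93 ± 0.25 and the matrix Gla protein gene Mgp by 0.51 ± 0.18 (adjusted p 0.0222). Of 10 cartilage genes 9 were higher (10 over the list alone; median 1.36), and of 18 osteochondrogenic genes 10 were higher and 0 lower (10 and 0 over the list alone; median 0.76). Matrix protease and inhibitor genes were higher in 15 of 18 cases and lower in 2 (15 and 2 over the list alone).

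Wnt pathway genes changed in both directions in week 16. Sost, which vascular smooth muscle expresses as well as osteocytes, fell from 443 ± 62.5 to 216 ± 70.4 (log2 change -1.10 ± 0.20, adjusted p 2.64e-06, n = 10 and 10), with ranges of 321 to 538 and 100.4 to 343. Axin2 changed by -0.30 ± 0.12 (adjusted p 0.0475). Frzb, a secreted Wnt-binding antagonist of cartilage, rose by 2.23 ± 0.24 and Dkk2, a ligand of the LRP co-receptors, by 1.38 ± 0.15. Of 13 canonical Wnt targets 4 were higher and 7 lower (4 and 7 over the list alone), and camera did not call the list (adjusted p 0.782). Acta2 fell from 8900 ± 717 to 5533 ± 1012 (-0.70 ± 0.16, adjusted p 0.000304), and 12 of 15 contractile genes were lower (14 over the list alone), a list call lost with an estimated correlation (adjusted p 0.419). In limma 5365 genes passed, 2274 higher and 3091 lower. The foamy macrophage (adjusted p 0.000167), lysosome (0.0174), cytokine (0.0174), protease (0.0156), cartilage (0.0354) and osteochondrogenic (0.0269) calls held with an estimated correlation.

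**Figure D2:**
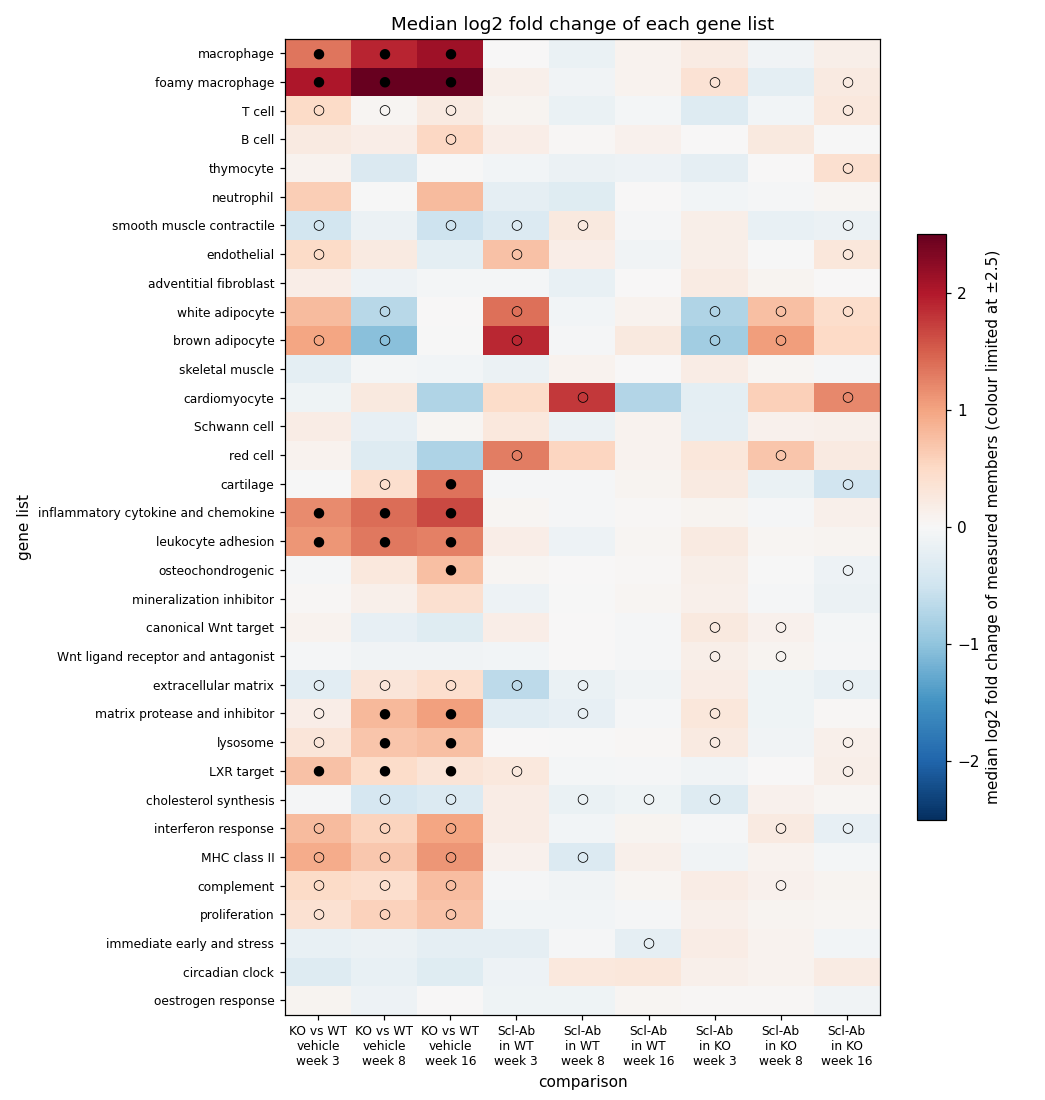
Median log2 change of the measured members of each gene list (y axis) in 9 comparisons (x axis), with filled circles where camera passed with an estimated correlation and open circles where it passed with the preset correlation alone. The foamy macrophage median in vehicle-treated knockouts was 2.03 in week 3 and 3.18 in week 16.

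The knockout effect on several cartilage and bone genes differed between days. From week 3 to week 16 the knockout change rose by 6.27 ± 0.72 for Col2a1, 4.62 ± 0.63 for Ibsp, 3.91 ± 0.77 for Spp1 and 1.36 ± 0.27 for Alpl (adjusted p 0.000381). Runx2 gained 0.41 ± 0.11 (adjusted p 0.0135) and Cd68 1.102 ± 0.32 (adjusted p 0.0254), while Wnt5a, a ligand of non-canonical Wnt signalling, lost ground (-0.79 ± 0.20). Sost did not pass this test (-0.64 ± 0.29, adjusted p 0.220). By week 8 the gain of Col2a1 (3.35 ± 0.80, adjusted p 0.0302), the lysosomal glycoprotein gene Gpnmb (1.97 ± 0.40) and the lipid-sensing receptor gene Trem2 (1.69 ± 0.38) had passed. The interaction called 617 genes for week 16 against week 3 (482 with a higher knockout change) and 40 for week 8 against week 3. The latter count was 14, 61 and 22 without wild-type vehicle replicates 3, 4 and 5 of week 8. With libraries of high carry-over left out, and so fewer samples, the counts were 99 and 1, and with array weights 3821 and 2549. Of 100 splits of the libraries 5 and 9 gave as many calls as 617 and 40. These splits shuffled genotype and so assume no knockout effect at all, which does not test whether the effect changed between days. For week 16 the foamy macrophage (adjusted p 0.00672), cartilage (0.00672) and osteochondrogenic (0.00672) lists held with an estimated correlation, with 12 of 18, 9 of 10 and 10 of 18 genes higher (over the list alone 14, 10 and 11). Each sampling day had its own animals and age, and the 3 sequencing batches named in the study's text are not assigned to libraries, so day, age and batch were not separated.

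In Scl-Ab libraries the knockout differed from wild type in many of the genes called under vehicle. Spp1 was higher by 6.57 ± 0.60, 7.91 ± 0.53 and 7.57 ± 0.54 in weeks 3, 8 and 16, and Cd68 by 3.20 ± 0.25, 3.83 ± 0.22 and 4.03 ± 0.22. Col2a1 was higher by 5.31 ± 0.51 in week 16, Runx2 by 0.64 ± 0.08 and Alpl by 1.43 ± 0.19. Sost fell from 423 ± 85.6 to 147 ± 58.2 in week 16 (-1.62 ± 0.21, adjusted p 2.24e-10, n = 8 and 10), and changed by -0.80 ± 0.20 in week 8 (adjusted p 0.000963). Counts in limma were 3764, 4719 and 6421. Week 3 gave 2257 and 1751 without wild-type Scl-Ab replicates 2 and 4. Genes called in both vehicle and Scl-Ab libraries numbered 1006 in the same direction and 135 in opposite directions in week 3 (467.8 shared by chance if independent), 1776 and 1 in week 8 (352.9), and 4644 and 0 in week 16 (1213). Across genes, which are not independent replicates, Pearson's r of these 3 relations was 0.290, 0.848 and 0.934, and Spearman's rho 0.0778, 0.597 and 0.839. With tissue scores in the model, set beside this after the data were seen, r was 0.735, 0.879 and 0.943 and rho 0.475, 0.660 and 0.845, with 1033 genes of week 3 called in the same direction and 5 in opposite directions. With a pseudocount of 0.1 the r of week 3 was 0.400. The cartilage call of week 16 (8 of 10 higher, 8 over the list alone) was lost with an estimated correlation (adjusted p 0.327).

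Scl-Ab in wild-type mice of week 3 went with lower matrix transcripts, Fkbp5 and Zbtb16 and higher fat transcripts. Eln fell from 942 ± 359.8 to 265 ± 117.7 (log2 change -1.85 ± 0.29, adjusted p 1.19e-05, n = 8 and 6), and Lox, the enzyme that cross-links collagen and elastin, from 88.8 ± 16.7 to 31.4 ± 5.46 (-1.47 ± 0.22). Libraries of the groups did not overlap in Lox, while Eln was 400 in vehicle replicate 4 and 427.3 in Scl-Ab replicate 6. Col3a1, a fibrillar collagen, changed by -0.98 ± 0.18. Of 21 extracellular matrix genes 18 were lower (18 over the list alone; median -0.65), a list call lost with an estimated correlation (adjusted p 0.929). Fkbp5 fell from 161 ± 77.5 to 43.6 ± 46.5 (-2.44 ± 0.49, adjusted p 0.000274) and Zbtb16, another glucocorticoid target, changed by -2.22 ± 0.46. Ucp1, the uncoupling protein of brown fat, rose from 455 ± 564 to 1557 ± 1100 (2.17 ± 0.81, adjusted p 0.0363), in step with 9 of 11 brown (9 over the list alone) and 8 of 13 white adipocyte genes (10 higher and 1 lower over the list alone), list calls lost with an estimated correlation as well (adjusted p 0.929 and 0.929). Among Wnt genes Axin2 rose from 1.47 ± 0.604 to 3.17 ± 1.35 (0.73 ± 0.15, adjusted p 0.000374) and the secreted antagonist gene Wif1 changed by -0.80 ± 0.23. Axin2 was highest in Scl-Ab replicates 2 and 4 (5.577 and 3.739), which also had the highest Ucp1 of that group (2517 and 3125). Scl-Ab replicate 1 was lowest of its group in both (1.758 and 228.9), and vehicle replicate 4 highest of its group in both (2.741 and 1736). The Axin2 rise was thus not separated from carried-over fat. Sost (-0.23 ± 0.24, adjusted p 0.501) and Spp1 (-1.02 ± 0.62, adjusted p 0.222) did not pass.

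The week 3 calls in wild type, those of matrix, fat and Wnt genes included, changed with the model. Limma called 3937 genes, 2008 higher and 1929 lower, and 2057 and 2225 without Scl-Ab replicates 2 and 4. With scores of 5 kinds of carried-over tissue in the model 693 passed, and with 2 components of the clock genes 0 did. The median change of the called genes went from 0.435 to 0.231 with the former and to 0.247 with the latter, while their SE went from 0.128 to 0.110 and 0.135. No list call of this comparison held with an estimated correlation. Ucp1, itself a member of the brown adipocyte score, turned to -0.0889 with the tissue scores.

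**Figure D3:**
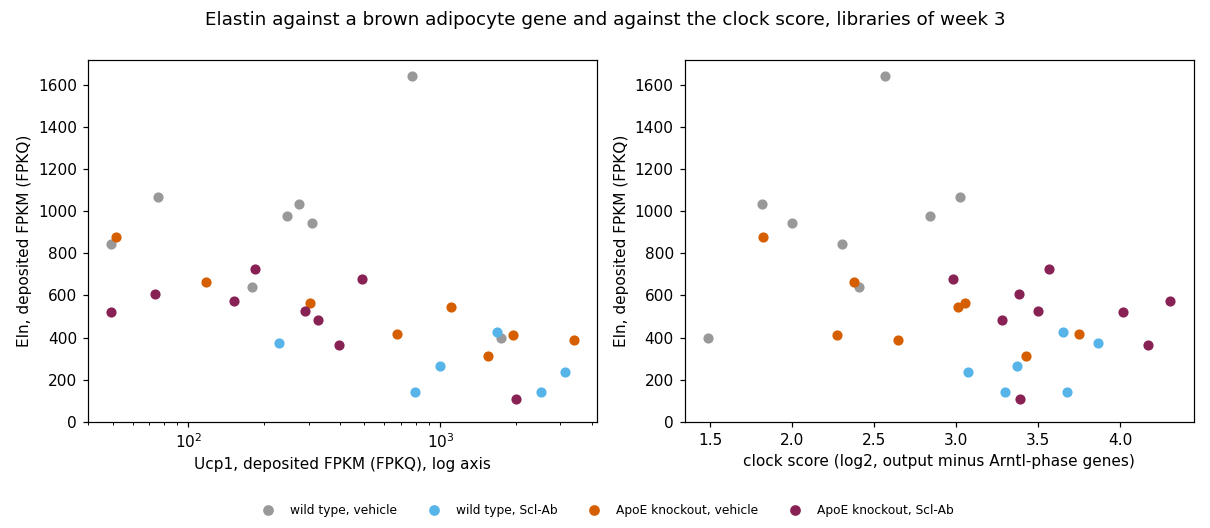
Deposited value of Eln (y axes) against that of Ucp1 (left, log axis) and against the clock score (right, log2 units) in each library of week 3, with colour for the group. Mean Eln was 942 in wild-type vehicle and 265 in wild-type Scl-Ab libraries.

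Wild-type aortas showed 0 calls in week 8 and 1 in week 16 in the model used throughout. In week 8 Eln, Axin2 and every other gene stayed above the threshold, with 0 of 14637 called by limma, 1497 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0744. Axin2 stood at 1.50 ± 0.186 and 1.84 ± 0.502 (0.17 ± 0.16, adjusted p 0.794, n = 5 and 9). Eln ran from 191.5 to 278.0 in Scl-Ab replicates 1 to 4 and from 444.8 to 1030 in replicates 5 to 9, against 584.8 to 1134 under vehicle, a division of the Scl-Ab group noticed in the values and shared with the clock score. The count was about 1.1e+02 with carry-over scores in the model, 171 with array weights, 84 with replicate number as a block, 22 with the run of animal numbers and 9 without a filter on low values. It reached 40 without vehicle replicate 3, 43 without Scl-Ab replicate 5, 1 without replicate 7 and 5 without replicate 9. In week 16 the predicted gene Gm6793 (chromosome 8, 112013433 to 112015036, named by a symbol alone) fell from 3.48 ± 0.421 to 1.96 ± 0.305 (-0.60 ± 0.12, adjusted p 0.0418, n = 10 and 8), with ranges of 2.73 to 4.10 and 1.57 to 2.44. It was the single call in limma, beside 797 genes at an unadjusted p under 0.05, and the count was 0 with a pseudocount of 0.1, 110 with array weights and 3 with carry-over scores. Leaving out vehicle replicate 1, 3, 5, 7 or 10 or Scl-Ab replicate 1, 2, 4 or 5 gave 0, vehicle replicates 2, 4, 6, 8 and 9 gave 5, 3, 2, 3 and 2, and Scl-Ab replicates 7 and 8 gave 3 and 4. The immediate early gene list was lower in week 16 (adjusted p 1.47e-07, 4 of 15 over the list alone), a call lost with an estimated correlation (adjusted p 0.437). Sost, Spp1, Runx2, Alpl, Cd68, Ccl2 and Il1b each had an adjusted p of 0.9997 in week 16.

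Knockout aortas under Scl-Ab in week 3 had less Fkbp5 and Zbtb16 and more Wnt5a and Mmp12. Fkbp5 fell from 66.8 ± 47.0 to 11.6 ± 3.36 (log2 change -2.12 ± 0.44, adjusted p 0.00157, n = 8 and 9) and Zbtb16 changed by -2.001 ± 0.42. Wnt5a rose from 9.99 ± 2.19 to 15.6 ± 2.90 (0.60 ± 0.15, adjusted p 0.00536), Dkk2 by 0.68 ± 0.16 and the Wnt-induced inhibitor gene Apcdd1 by 0.45 ± 0.15, which turned to -0.0201 with tissue scores and clock components together. Mmp12 rose by 0.95 ± 0.27 (adjusted p 0.0178), Trem2 by 0.78 ± 0.25 and Gpnmb by 0.78 ± 0.26, while Cd68 (0.64 ± 0.23, adjusted p 0.0590) and Spp1 (1.34 ± 0.56, adjusted p 0.106) did not pass. The small nuclear RNA gene Rn7sk (1.80 ± 0.33) and the ribosomal RNA-like AY036118 (1.25 ± 0.35) were among the highest changes, and replicate 9 of the Scl-Ab group, the library with the lowest correlation with its group (0.902), held the top AY036118 value in a range of 644 to 67100. Sost (-0.22 ± 0.21, adjusted p 0.531) and Axin2 (-0.02 ± 0.14, adjusted p 0.932) did not pass. Limma called 1339 genes, 807 of them higher. Without vehicle replicates 1, 3 and 6 it called 554, 676 and 880, and without Scl-Ab replicates 5, 7 and 9 it called 787, 874 and 3512. Transcripts of fat were lower too, with median changes of -0.87 for brown and -0.76 for white adipocyte genes (adjusted p 0.882 for both with an estimated correlation). With tissue scores in the model 1430 genes passed, with clock components 957 and with both together 5, and no list call held with an estimated correlation (canonical Wnt targets, 2 of 13 higher, 5 over the list alone, adjusted p 0.690).

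In week 8 the knockout response again joined lower Fkbp5 with higher Wnt5a. Fkbp5 fell from 129 ± 51.01 to 44.0 ± 39.4 (-1.82 ± 0.41, adjusted p 0.00930, n = 10 and 10). Wnt5a rose from 6.33 ± 1.95 to 10.8 ± 2.74 (0.70 ± 0.13, adjusted p 0.00225), with ranges of 3.28 to 10.7 and 7.04 to 16.1. Apcdd1 rose by 0.61 ± 0.13 (adjusted p 0.00930), the ligand genes Wnt9a by 0.41 ± 0.12 and Wnt10b by 0.35 ± 0.10. The clock repressor gene Per3 rose by 0.85 ± 0.21 and the clock activator gene Arntl changed by -0.95 ± 0.24, which turned to -0.0901 and 0.146 with clock components built in part from these genes. Axin2 (0.33 ± 0.12, adjusted p 0.133), Sost (-0.20 ± 0.20, adjusted p 0.644) and Spp1 (-0.33 ± 0.51, adjusted p 0.787) did not pass. Of 13 canonical Wnt targets 1 was higher (4 over the list alone), and the list's call (adjusted p 0.00348) was lost with an estimated correlation (0.1). Limma called 265 genes, 162 of them lower, and none of those also called in week 3 had the opposite direction there. Without vehicle replicates 4, 5, 7, 8 and 10 the count was 138, 97, 125, 142 and 550. Without Scl-Ab replicates 1, 2, 3, 4, 6 and 9 it lay from 87 to 168, and without Scl-Ab replicates 5 and 8 it was 450 and 405. With clock components in the model it was 0, and the median change of the called genes went from 0.385 to 0.125.

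After 16 weeks no bone, cartilage or inflammatory gene of the fixed list passed in knockouts given Scl-Ab. Spp1 stood at 1978 ± 814 under vehicle and 2183 ± 948 under Scl-Ab (0.06 ± 0.51, adjusted p 0.959, n = 10 and 10), Runx2 at 1.09 ± 0.286 and 1.17 ± 0.242 (0.06 ± 0.07, adjusted p 0.716), and Cd68 at 155 ± 57.8 and 180.1 ± 40.7 (0.26 ± 0.21, adjusted p 0.549). Ccl2 (0.21 ± 0.34, adjusted p 0.772), Il1b (-0.11 ± 0.22, adjusted p 0.822), Alpl (-0.13 ± 0.18, adjusted p 0.736) and Sost (-0.60 ± 0.20, adjusted p 0.166) did not pass either. Of 10 cartilage genes 5 were lower adjusted over the list alone and 0 over all genes (median -0.48, adjusted p 0.000183), and that list call was lost with an estimated correlation (0.819). The genes called were Gm6793, which fell from 2.74 ± 0.477 to 1.60 ± 0.559 (-0.54 ± 0.11, adjusted p 0.0485), and Dennd4a, an exchange factor for Rab GTPases on chromosome 9, which fell from 6.30 ± 1.04 to 4.45 ± 0.536 (-0.41 ± 0.09, adjusted p 0.0485). Limma thus called 2 genes, beside 2103 at an unadjusted p under 0.05, and 0 with a pseudocount of 0.1. The count was 0 without vehicle replicate 1, 3, 4, 5, 6, 7, 9 or 10 or Scl-Ab replicate 1, 2, 3, 4, 6, 7 or 9, 1 without vehicle replicate 2, 86 without Scl-Ab replicate 5 and 1 without Scl-Ab replicate 8. In simulated data of the same sizes and spread this comparison recovered 83.6% of genes changed 1.5-fold and 91.04% of genes changed 2-fold. Those data had independent noise per gene and folds added to log2(value + 1), which for low genes means a larger change of the value. They do not show which changes would have been found in the real libraries.

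**Figure D4:**
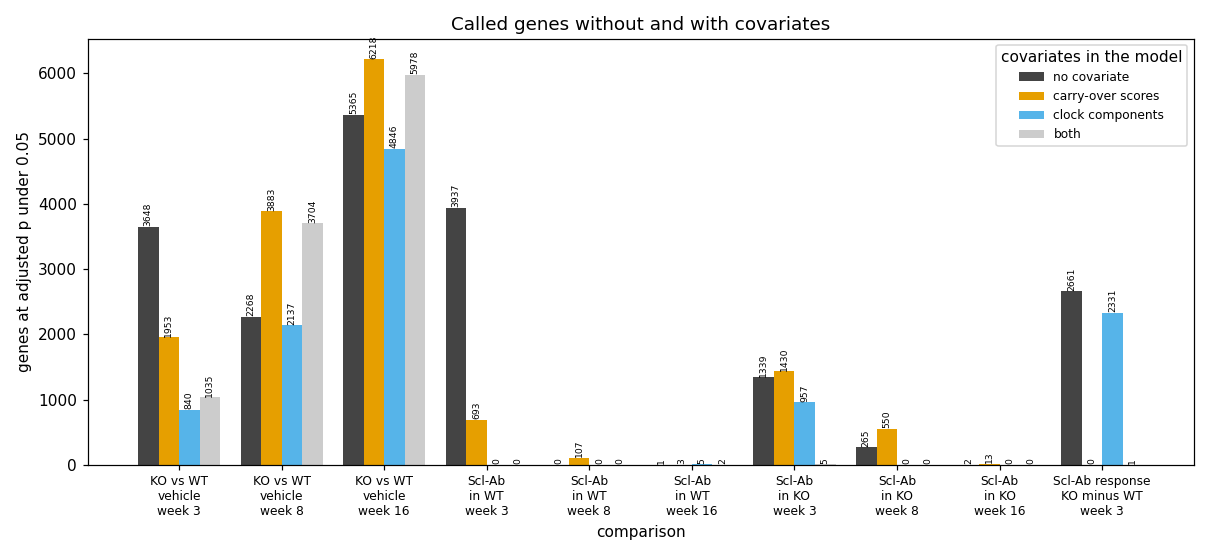
Number of genes called by limma (y axis) in 10 comparisons (x axis), without a covariate, with carried-over tissue scores, with clock components, and with both. Without a covariate Scl-Ab called 3937, 0 and 1 genes in wild type and 1339, 265 and 2 in the knockout in weeks 3, 8 and 16.

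In the model used throughout, the Scl-Ab response was called different between genotypes in week 3. Taking the wild-type response from the knockout response, Eln gained 1.74 ± 0.39 (adjusted p 0.00483), Ucp1 changed by -3.40 ± 1.09 (adjusted p 0.0213), Axin2 by -0.75 ± 0.20 (adjusted p 0.00791) and Spp1 by 2.36 ± 0.83 (adjusted p 0.0359). Of 21 extracellular matrix genes 17 were higher (20 over the list alone) and of 11 brown adipocyte genes 9 lower (10 over the list alone), both lost with an estimated correlation (adjusted p 0.638 each). The limma interaction called 2661 genes in week 3 (4742 at an unadjusted p under 0.05). It called 0 with tissue scores in the model and 0 in a fit on the libraries of week 3 alone. The count was 4340 without wild-type vehicle replicate 4, 1382 without knockout vehicle replicate 1, 1389 and 1025 without wild-type Scl-Ab replicates 2 and 4, and 4276 without knockout Scl-Ab replicate 9. It called 0 genes in week 8 (1037 unadjusted) and 0 in week 16 (309 unadjusted). In week 8 the count was 4 without wild-type vehicle replicate 3, and 1 without knockout vehicle replicate 1, knockout vehicle replicate 9 or wild-type Scl-Ab replicate 9. The canonical Wnt target list of week 8 was higher (adjusted p 0.00178, 3 of 13 over the list alone), a call lost with an estimated correlation (0.0906).

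Averaged over the 3 times, Arntl was lower and Per3 higher in Scl-Ab than in vehicle libraries of both genotypes. Eln and Axin2 are given for wild type and Wnt5a for the knockout, but none of these genes passed the test of a difference between genotypes. In wild type Eln changed by -1.11 ± 0.16 (adjusted p 3.18e-06), Axin2 rose by 0.35 ± 0.08 (adjusted p 0.00233), Arntl changed by -0.98 ± 0.16 and Per3 by 0.83 ± 0.14. Of the single times, Eln and Axin2 passed in week 3 alone, where the Axin2 rise was not separated from carried-over fat. In the knockout Wnt5a rose by 0.48 ± 0.08 (adjusted p 1.73e-05), Wnt9a by 0.31 ± 0.07, Wnt11, a ligand of heart and smooth muscle development, by 0.34 ± 0.08 and Apcdd1 by 0.29 ± 0.08. Sost changed by -0.34 ± 0.12 (adjusted p 0.0338), Fkbp5 by -1.38 ± 0.24, Arntl by -0.86 ± 0.14 and Per3 by 0.71 ± 0.13. Of 27 Wnt ligand, receptor and antagonist genes 8 were higher and 2 lower in the knockout (8 and 2 over the list alone), and camera did not call the list (adjusted p 0.0605). Clock genes were higher in 6 and lower in 4 of 15 cases in wild type and higher in 6 and lower in 5 in the knockout (over the list alone 6, 4, 7 and 5). Limma called 2333 genes in wild type and 2365 in the knockout, and 0 in either with clock components in the model. The difference of these means passed for Ephb2, a receptor of ephrin-B ligands (0.51 ± 0.09, adjusted p 0.00495), and Kazn, a desmosome-associated protein (0.32 ± 0.06, adjusted p 0.0122), and for no other gene, with 1253 at an unadjusted p under 0.05.

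Clock genes shifted with Scl-Ab in both genotypes. The clock score is the mean log2 of the output and repressor genes Dbp, Tef, Hlf, Per3, Nr1d2 and Ciart minus that of the activators Arntl, Npas2 and Clock. These 9 of the 15 genes of the fixed list were chosen after the data were seen, so the score describes the shift, and p-values are given for a score of all 15, also set up then (the others minus Arntl, Npas2, Clock and Nfil3). The 9-gene score was 1.18, 1.17 and 1.22 higher with Scl-Ab in wild type in weeks 3, 8 and 16, and 0.825, 1.02 and 1.03 higher in the knockout. In wild type in week 8 Scl-Ab replicates 1 to 4 stood apart at 3.588 to 4.037, while replicates 5 to 9 (1.241 to 2.69) lay within the vehicle range (1.056 to 2.756). Over all 15 genes the difference in wild type was 0.978 in week 3 (exact permutation test of 3003 splits, two-sided, p 0.00167, adjusted over 12 tests 0.0118; n = 6 and 8), 1.08 in week 8 (exact p 0.0395, adjusted 0.0789; n = 9 and 5) and 1.04 in week 16 (exact p 0.00338, adjusted 0.0135; n = 8 and 10). Knockouts differed by 0.633 in week 3 (exact p 0.0262, adjusted 0.0628; n = 9 and 8), 0.930 in week 8 (exact p 0.00196, adjusted 0.0118; n = 10 and 10) and 0.891 in week 16 (exact p 0.00770, adjusted 0.0231; n = 10 and 10). Vehicle-treated knockouts exceeded vehicle-treated wild types by 0.457, 0.394 and 0.225 over the 15 genes, which did not pass (adjusted exact p 0.183, 0.435 and 0.484). Per1 and Nr1d1, both of the list, did not follow the score (loadings on the first component of the list -0.0671 and -0.0413, against 0.390 for Per3). Group means of the 9-gene score were lower on later days, in wild-type vehicle 2.31 ± 0.519 in week 3, 1.68 in week 8 and 0.376 in week 16. These genes follow the hour of harvest in any tissue, and the labels give no hour.

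**Figure D5:**
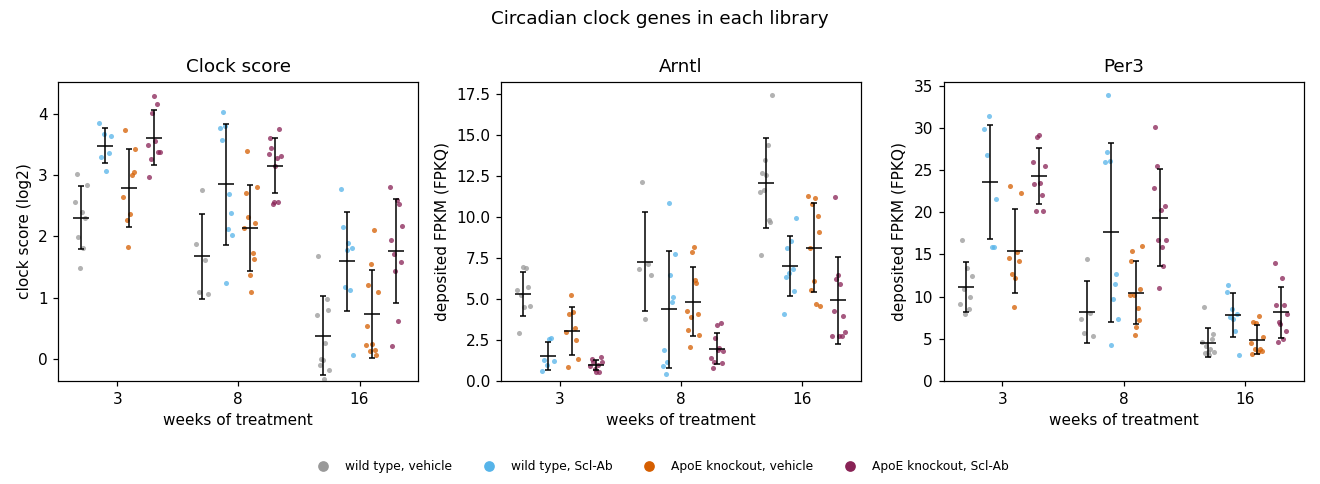
Clock score (left, log2 units) and deposited values of Arntl and Per3 (y axes) of each library by weeks of treatment (x axes), with colour for the group and bars for mean and SD. Wild-type mean scores in week 3 were 2.31 under vehicle and 3.49 under Scl-Ab.

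Genes of the knockout signature, taken from vehicle libraries of another day, moved under Scl-Ab as sets by mean log2 changes of -0.142 to 0.0900 in 12 tests. The farthest was the set of genes lower in the knockout, in wild type in week 3 (-0.142, camera adjusted p 1.81e-12, with an estimated correlation 0.178). In knockouts the genes higher in the signature moved by 0.0900 in week 3 (adjusted p 3.32e-05, estimated correlation 0.663), 0.00652 in week 8 (0.0672 and 0.689) and 0.0812 in week 16 (2.10e-10 and 0.229). Genes lower in the signature moved in knockouts by -0.118 in week 16 (2.01e-23 and 0.0332). Of the 12 tests 9 passed, and the last of these alone held with an estimated correlation. Across genes, which are not independent replicates, Scl-Ab changes of wild type and knockout had a Pearson's r of -0.246, 0.188 and 0.287 in weeks 3, 8 and 16 (Spearman's rho -0.0628, 0.182 and 0.385). With tissue scores in the model r was 0.281, 0.252 and 0.318 (rho 0.275, 0.237 and 0.328). Between days of the knockout r was -0.0129 (weeks 3 and 8), 0.447 (weeks 8 and 16) and -0.0705 (weeks 3 and 16), with rho 0.122, 0.376 and 0.0344, and with tissue scores r was 0.361, 0.162 and 0.424 (rho 0.365, 0.133 and 0.471). In wild type r was 0.160, 0.1045 and 0.277 in the same order (rho 0.216, 0.222 and 0.322), and 0.313, 0.164 and 0.287 with tissue scores (rho 0.299, 0.200 and 0.307).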

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

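Tests chosen after the result was seen were the count of calls left with carry-over scores, the 3 tests of the clock score and all splits of the libraries into other groups.

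Osteopontin, smooth muscle actin and bone genes had single libraries apart from their group. Of 168 sets of a measure and a group (13 genes and relative depth in 12 groups), 29 had a highest or lowest library whose gap to the next exceeded Dixon's 95% limit. For normal values chance gives about 1 in 20, or 8.4, but these values were not log-transformed. Skewed values and values near 0, as of Bglap, can exceed the limit more often, so the excess alone does not mark faulty libraries. Replicate 4 of wild-type vehicle, another animal each time, stood out, with highest values unless marked low: in week 3 with Acta2 at 3133 (low), Ccl2 at 8.76 and Il1b at 1.28, in week 8 with Spp1 at 176.6, Runx2 at 1.13, Mgp at 16140, Tnfrsf11b at 44.5 and Acta2 at 5357 (low), and in week 16 with Spp1 at 21.1 and Acta2 at 7125 (low). Knockout vehicle replicate 4 of week 3 had Spp1 at 1106, Cd68 at 158.0, Tnfrsf11b at 20.01 and Bglap at 0.118, all highest. Knockout vehicle replicate 3 of week 8 led its group in Bglap (2.78), Alpl (15.4) and Mgp (19100).

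Other libraries stood apart in 1 or 2 genes, with the highest value unless stated. Knockout Scl-Ab replicate 9 of week 3 had the highest Axin2 (4.399, others 0.991 to 2.35) and the lowest Mgp (2672). In week 3 wild-type vehicle replicate 8 had Bglap at 0.486, wild-type vehicle replicate 2 had Tnfrsf11b at 15.2, and wild-type Scl-Ab replicate 1 had Spp1 at 4.66. In week 8 Bglap was 0.307 in wild-type vehicle replicate 2 and 0.576 in knockout Scl-Ab replicate 9, and Ccl2 was 10.5 in wild-type Scl-Ab replicate 2. In week 16 knockout vehicle replicate 10 had the highest Ccl2 (34.96) and Il1b (8.22), wild-type Scl-Ab replicate 6 had Il1b at 3.12, and wild-type Scl-Ab replicate 2 had Axin2 at 2.30.

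Effects that differed between groups numbered 2661 genes for the Scl-Ab response between genotypes in week 3, 2 for its mean over the 3 times, 40 for the genotype effect between weeks 8 and 3, and 617 between weeks 16 and 3. Of 100 splits of the libraries, the real one included, 4 called as many as the 2661 (highest other 3599), without adjustment for the other comparisons. These splits shuffled treatment within genotype and day, and so assume no Scl-Ab effect in either genotype. They cannot exclude chance for a difference between the genotypes. In place of 2661 the count was 0 with carry-over scores in the model and 0 in a fit on the libraries of week 3 alone. For the count of 2, split in the same way, 5 splits called as many (highest other 423), so chance was not excluded. For 40 (9 splits, highest other 2467) and 617 (5 splits, highest other 1824) the splits shuffled genotype within day and treatment. That assumes no knockout effect at all. Such splits cannot decide whether the effect changed between days, and chance stays open. Splits of genotype mix knockouts with wild types, so splits with many calls can follow from the scheme itself. The 423 calls against the real 2 point to a structure of the samples, and what it is was not tested.

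Eln, Ucp1 and Fkbp5 were among the 3937 Scl-Ab calls of wild type in week 3, and the structure behind the calls was weighed. Slopes on the carry-over scores within the groups of other days predicted the sign of 93.49% of those genes, and slopes on the clock components 97.23%. For the calls of knockouts in week 3 they predicted 61.61% and 72.58%, and 87.72% together. For the calls of the difference between genotypes in week 3 they predicted 94.55% and 89.32%. The slope of observed on predicted change was 1.44 and 6.992 for that difference, against 1.648 and 1.669 in wild type. With clock components in the model 2331 genes were still called for the difference. Its matching signs thus do not show that the clock components account for the size of the change. Shares of matching signs for random lists were not computed. Tissue left at dissection and the hour of harvest could thus each lie behind much of the pattern in wild type. With the carry-over scores in the model 667 genes were still called in the same direction. Such scores are means of a few gene lists and may remove only part of a carry-over effect. The 667 calls thus cannot decide whether carried-over tissue was the whole cause. Components of matched random lists left as few calls as the clock components, 0, in 6 of 100 draws. The median draw left 951 and the highest 4551, with a median SE ratio of 0.9645 against 1.124 for the clock components, so the typical draw did not act like them, while a stand-in for the treatment in general was not excluded. With clock components the fold of called genes fell from 0.435 to 0.247 while the SE rose from 0.128 to 0.135. A response to Scl-Ab itself stays open.

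The clock genes themselves were the second pattern. The scores of carried-over tissue did not account for it, since the mean Scl-Ab change of the clock score was 7.518 standard errors with those scores in the model and 7.821 without (7.369 and 7.596 over all 15 genes of the list). Carried-over tissue that these scores miss was not excluded. An effect of Scl-Ab alone and an order of harvest by group cannot be told apart: vehicle knockouts and wild types differed at 0 of 3 times at an adjusted p under 0.05, and the labels give no harvest times. Within groups the clock score fell with the animal number in the labels (Pearson's r -0.220, permutation p 0.03665; Spearman's rho -0.222, p 0.0342; r without the 2 farthest libraries -0.188; 99 libraries, 1 relation tested). The prediction for harvest in number order, written after the result was seen, was that the score follows the number at a permutation p under 0.05. That was met. The prediction named no direction, and only the labelling of the test asked for a rise. The order of harvest is not given, so the fall neither shows nor excludes harvest in number order. Numbers could also follow cage or weight.

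Genes around Apoe were the third. Of 220 tested genes within 10 Mb of Apoe 38 (17.3%) passed in vehicle knockouts at all 3 times, against 8.65% of genes elsewhere, and 97.17% of other windows of that width across the genome had a lower share. Flanking DNA from the embryonic stem cell strain of the knockout may therefore lie behind part of the calls near Apoe, Bcam and Bcl3 among them. No biological explanation was tested.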

How the results depend on the processing

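Chosen after the data were seen were the tests with clock components, alone or with carry-over scores, with libraries of high carry-over left out and with the run of animal numbers, and both clock scores. Depth in reads is unknown, so no value here has a counting error, and leaving out single libraries was run for counts of genes alone. Counts below are given where they moved by more than 1.5 times, and the cause was not tested unless stated.

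Apoe, Cd68, Spp1 and the other genes named in the text, 124 changes in all, kept direction and side of the threshold in 1184 results under the alternatives fixed in advance, gained the call in 11 and turned in 2, and lost the call in the others. Under the added alternatives 373 stayed, 105 lost the call, 1 gained it and 17 turned. The 47 named list results stayed in 240 and lost the call in 29 under fixed alternatives (25 of these with an estimated correlation) and stayed in 85 and lost it in 7 under added ones.

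With a 1.5-fold minimum, which removes genes by construction, counts were 958 (week 3), 881 (week 8) and 1373 (week 16) for the knockout effect under vehicle, 1369 (week 3), 1147 (week 8) and 1772 (week 16) for the knockout effect under Scl-Ab, 1226 (week 3) and 57 (mean over time) for Scl-Ab in wild type, 137 (week 3), 57 (week 8), 0 (week 16) and 32 (mean over time) for Scl-Ab in the knockout, and 1572 (week 3) and 0 (mean over time) for the difference of the Scl-Ab response. With a pseudocount of 0.1 they were 0 (week 16) for Scl-Ab in wild type, 0 (week 16) for Scl-Ab in the knockout, and 21 (weeks 8 and 3) for the change of the knockout effect between days. Without a filter on low values they were 9 (week 8) and 5 (week 16) for Scl-Ab in wild type, 110 (week 8) and 5 (week 16) for Scl-Ab in the knockout, and 5 (week 8) for the difference of the Scl-Ab response. With a filter of 5 they were 0 (week 16) for Scl-Ab in wild type, 0 (week 16) for Scl-Ab in the knockout, and 0 (mean over time) for the difference of the Scl-Ab response. Rescaling by median of ratios gave 0 (week 16) for Scl-Ab in the knockout. Quantile normalization gave 0 (week 16) for Scl-Ab in wild type and 0 (week 16) for Scl-Ab in the knockout. Array weights gave 7392 (week 3) for the knockout effect under vehicle, 6302 (week 3), 171 (week 8), 110 (week 16) and 5639 (mean over time) for Scl-Ab in wild type, 4876 (week 3), 1927 (week 8), 1 (week 16) and 4615 (mean over time) for Scl-Ab in the knockout, 6031 (week 3) and 2564 (mean over time) for the difference of the Scl-Ab response, and 2549 (weeks 8 and 3) and 3821 (weeks 16 and 3) for the change of the knockout effect between days. Replicate numbers are not known to pair samples. The mean correlation of residuals of libraries with the same number was -0.0450, 0.0835 and 0.0213 in weeks 3, 8 and 16. For other pairs it was 0.0103, -0.00883 and -0.00104. The best match in another group had the same number for 1 of 31, 10 of 34 and 5 of 38 libraries, so pairing in week 8 was not excluded. A block for replicate number gave 84 (week 8) and 0 (week 16) for Scl-Ab in wild type, 3395 (week 3) and 1 (week 16) for Scl-Ab in the knockout, 2 (week 8) and 9 (mean over time) for the difference of the Scl-Ab response, and 14 (weeks 8 and 3) for the change of the knockout effect between days. Fits on the libraries of a day alone, with fewer samples, gave 2181 (week 3) for the knockout effect under vehicle, 1264 (week 3) for the knockout effect under Scl-Ab, 1444 (week 3) for Scl-Ab in wild type, 203 (week 3), 68 (week 8) and 1 (week 16) for Scl-Ab in the knockout, and 0 (week 3) for the difference of the Scl-Ab response. Fits on the compared groups alone, with fewer samples, gave 1658 (week 3) for the knockout effect under vehicle, 989 (week 3) for the knockout effect under Scl-Ab, 892 (week 3) for Scl-Ab in wild type, 40 (week 3), 521 (week 8) and 1 (week 16) for Scl-Ab in the knockout, 0 (week 3) for the difference of the Scl-Ab response, and 4 (weeks 8 and 3) for the change of the knockout effect between days.

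Counts moved with covariates as well. Carry-over scores in the model gave 1953 (week 3) and 3883 (week 8) for the knockout effect under vehicle, 693 (week 3), about 1.1e+02 (week 8) and 3 (week 16) for Scl-Ab in wild type, 550 (week 8) and 13 (week 16) for Scl-Ab in the knockout, 0 (week 3) and 1 (mean over time) for the difference of the Scl-Ab response, and 8 (weeks 8 and 3) for the change of the knockout effect between days. Clock components gave 840 (week 3) for the knockout effect under vehicle, 2983 (week 8) for the knockout effect under Scl-Ab, 0 (week 3), 5 (week 16) and 0 (mean over time) for Scl-Ab in wild type, and 0 (week 8), 0 (week 16) and 0 (mean over time) for Scl-Ab in the knockout. Both together gave 1035 (week 3) and 3704 (week 8) for the knockout effect under vehicle, 1747 (week 3) for the knockout effect under Scl-Ab, 0 (week 3), 2 (week 16) and 0 (mean over time) for Scl-Ab in wild type, 5 (week 3), 0 (week 8), 0 (week 16) and 0 (mean over time) for Scl-Ab in the knockout, 1 (week 3) for the difference of the Scl-Ab response, and 14 (weeks 8 and 3) for the change of the knockout effect between days. Leaving out libraries of high carry-over, with fewer samples, gave 1785 (week 3) for the knockout effect under vehicle, 604 (week 3) and 2887 (week 8) for the knockout effect under Scl-Ab, about 1.1e+02 (week 3), 0 (week 16) and 671 (mean over time) for Scl-Ab in wild type, 826 (week 3), 76 (week 8) and 0 (week 16) for Scl-Ab in the knockout, 0 (week 3) and 0 (mean over time) for the difference of the Scl-Ab response, and 1 (weeks 8 and 3) and 99 (weeks 16 and 3) for the change of the knockout effect between days. The run of animal numbers gave 22 (week 8) and 0 (week 16) for Scl-Ab in wild type, 920 (week 8) for Scl-Ab in the knockout, and 1 (week 8) for the difference of the Scl-Ab response.

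Leaving out each library of the compared groups in turn, and for the change between days only the 5 wild-type vehicle libraries of week 8, gave counts of 2407 to 5901 (week 3) for the knockout effect under vehicle, 1751 to 5353 (week 3) for the knockout effect under Scl-Ab, 2057 to 5392 (week 3), 0 to 43 (week 8) and 0 to 5 (week 16) for Scl-Ab in wild type, 554 to 3512 (week 3), 87 to 550 (week 8) and 0 to 86 (week 16) for Scl-Ab in the knockout, 1025 to 4340 (week 3) and 0 to 4 (week 8) for the difference of the Scl-Ab response, 14 to 61 (weeks 8 and 3) for the change of the knockout effect between days. Within 1.5 times stayed 249 of these counts, and 75 did not. The change between weeks 16 and 3 had no such test.

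List calls fell from 177 to 39 with an estimated correlation, and signature tests from 9 to 1. Genes called alike for the knockout under vehicle and under Scl-Ab went to 2669 in week 8 with carry-over scores, an alternative chosen for this relation after the data were seen. Correlations across genes between Scl-Ab effects moved with carry-over scores to 0.281 (wild type and knockout, week 3), 0.313 (wild type, weeks 3 and 8), 0.361 (knockout, weeks 3 and 8), 0.162 (knockout, weeks 8 and 16) and 0.424 (knockout, weeks 3 and 16). With a pseudocount of 0.1 they moved to 0.176 (wild type and knockout, week 16) and 0.00273 (wild type, weeks 8 and 16).

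Over all 15 genes of the clock list, in place of 9, the clock score lost the call of knockouts in week 3 (difference 0.633, adjusted p 0.0628) and kept the side of the threshold in its 11 other comparisons. Some directions turned. With carry-over scores, of which the gene and lists are members by construction, Ucp1 went to -0.0889 for Scl-Ab in wild type in week 3 and 0.0192 for the difference between genotypes, the brown adipocyte median to -0.0889, -0.0697 (knockout, week 3) and -0.0119 (difference), the white adipocyte median to 0.0338 (knockout, week 3) and the cardiomyocyte median to 0.0718 (wild type, week 8). Where a list's median kept its sign, the sign of its test turned. Genes lower in the knockout in week 16 went to -0.00341 in knockouts of week 8. With clock components, of which Per3 and Arntl are members, Per3 went to -0.0901 (knockout, week 8), -0.0471 (wild type, mean over time) and -0.0541 (knockout, mean), Arntl to 0.146, 0.003495 and 0.0225 in the same order, and Fkbp5 to 0.123 (knockout effect, week 3). With both sets Ucp1 went to -0.167 and 0.0865, Per3 to -0.0803, -0.0353 and -0.0538, Arntl to 0.141 (knockout, week 8) and 0.0142 (knockout, mean), Fkbp5 to 0.115, and Apcdd1 to -0.0201 (knockout, week 3) and -0.0236 (mean). With libraries of high carry-over left out the cardiomyocyte median went to -0.0253 (knockout, week 16) and genes higher in the knockout in week 16 to -0.0532 in knockouts of week 8.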

Other observations

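Chosen after the result was seen were all splits of the libraries into other groups reported here.

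Antigen presentation, complement and cholesterol genes shifted in vehicle knockouts, and some T cell and B cell genes were called as well. Of 10 MHC class II genes 10 were higher in week 16 (over the list alone 10; median log2 change 1.096), 10 of 13 complement genes (10 over the list alone) and 13 of 14 proliferation genes (14 over the list alone). Genes of cholesterol synthesis, which cells lower when they take up sterol, were lower in 12 of 20 cases (12 over the list alone; median -0.34). These list calls were lost with an estimated correlation (adjusted p 0.163, 0.0600, 0.0600 and 0.419). T cell genes were higher in 3 of 9 cases (3 over the list alone) and B cell genes in 3 of 5 (3 over the list alone; estimated correlation 0.419 and 0.334). Of 19 immunoglobulin segments 3 were higher in week 16 and 0 in weeks 3 and 8 (limma; median log2 change 0.36, -0.21 and 0.04), and Scl-Ab called 0 of them in either genotype at any time.

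Transcripts of tissues that lie against the arch varied between the groups. Under Scl-Ab the median change of 11 cardiomyocyte genes was 1.76 in wild type in week 8 (adjusted p 0.00371; 0.858 with an estimated correlation) and 1.20 in knockouts in week 16 (0.00484; 0.819), with 0 single genes called by limma. Brown adipocyte genes moved by -0.87 and white adipocyte genes by -0.76 in knockouts in week 3 (adjusted p 0.0143 and 0.0143; estimated correlation 0.882 for both), against 1.88 and 1.37 in wild type. Camera did not call the 6 skeletal muscle genes in wild type in week 3 (median -0.16, adjusted p 0.393; 1 lower, 1 over the list alone), nor the 5 thymocyte genes (median -0.07, against a mean of 0.168 and a test pointing up, adjusted p 0.886; 1 higher, 0 over the list alone). Libraries with a score over 2.5 median absolute deviations above the median numbered 4 of 8 in wild-type vehicle and 4 of 6 in wild-type Scl-Ab in week 3, and 0 of 10 in knockout vehicle and 4 of 10 in knockout Scl-Ab in week 16.

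Some genes beside Apoe were called in the same direction each time in vehicle knockouts, 11 of 47 tested within 2 Mb, and 3 of these 11 were picked after their values were seen. The adhesion glycoprotein gene Bcam, 65.9 kb from Apoe, changed by -1.17, -0.84 and -1.31 in weeks 3, 8 and 16, and the NF-kB cofactor gene Bcl3, on the same side, by 1.46, 1.40 and 1.88. Apoc4, an apolipoprotein gene on the other side of Apoe, changed by 0.39, 0.80 and 0.81.

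Counts of called genes, of any kind among the 14637 tested, were set against other splits of the same libraries, 100 per comparison with the real one included. The real split alone reached its count for the knockout effect under vehicle in week 8 (2268 genes, highest other 1852) and week 16 (5365, highest other 3637). The same held under Scl-Ab in week 8 (4719, highest other 1341) and week 16 (6421, highest other 4515). It held as well for Scl-Ab in knockouts in week 8 (265, highest other 197) and for the knockout mean over the 3 times (2365, highest other 1247). For Scl-Ab in wild type 1 other split called more genes, in week 3 (3937, highest other 4526, 2 splits) and for the mean over the 3 times (2333, highest other 4723, 2 splits). A share of 1 in 100 is the lowest possible, and no share was adjusted for the other comparisons. Chance was thus not excluded for these counts of wild type. For the counts that the real split alone reached, the splits argue against chance before such adjustment. The splits alone did not exclude chance for the knockout effect in week 3 under vehicle (3648, highest other 4574, 5 splits) or Scl-Ab (3764, highest other 5237, 6 splits). In other animals under vehicle, 1325 of the 3648 genes were called in the same direction and 0 in the opposite one in week 8 (276.2 expected of independent lists), and 2429 and 11 in week 16 (675.9). Of the 3764 under Scl-Ab, 1006 were called in the same direction in vehicle animals of week 3 (467.8 expected) and 135 in the opposite one. Over all genes rho of that relation was 0.0778. The expected numbers take genes as independent. Genes that move together can exceed them by chance, so these overlaps cannot decide whether chance was the whole cause. For Scl-Ab in knockouts in week 3 (1339, highest other 4966, 8 splits) the splits did not exclude chance either. In other animals of week 8 about 1.1e+02 of these genes were called in the same direction and 0 in the opposite one (11.57 expected). This expected number also takes genes as independent, so the overlap cannot decide about chance. Over all genes rho was 0.122 with week 8 and 0.0344 with week 16. Chance could not be excluded for Scl-Ab in week 16 in knockouts (2, highest other 542, 10 splits) or in wild type (1, highest other 4, 11 splits). For the counts of 0, Scl-Ab in wild type in week 8 (highest other 361) and its difference between genotypes in week 8 (highest other 44) and week 16 (highest other 1), all 100 splits are as large by construction. Splits with several times the real count, as for 1339 and 2, point to a structure of the samples. For the 1339, slopes on carry-over scores and clock components from the groups of other days predicted the sign of 61.61% and 72.58% of genes apart, and 87.72% together. For the 2 the structure was not tested.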
